A study of Mus musculus with 60 samples.

How the data were processed

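Bacterial 16S rDNA was sequenced from the colon of ICR mice aged 10 weeks. ICR is an outbred laboratory stock. Per the labels' protocols, the colon was emptied of its contents and frozen, total DNA was extracted, and the amplicon libraries were sequenced by a standard Illumina HiSeq procedure. The 60 samples fall into 6 groups of 10, read from the treatment given in each sample's labels. The groups are an untreated control, AOS given at 10 mg/kg (AOS10), a high-fat diet with streptozotocin (HFD-STZ), HFD-STZ with AOS10, and HFD-STZ followed by faecal microbiota transplantation (FMT) from AOS10 donors or from control donors. AOS is not spelled out in the labels; the abbreviation is commonly used for alginate oligosaccharides. Streptozotocin is a compound toxic to pancreatic beta cells, used with a high-fat diet to make diabetic mice.

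The deposited values are counts, whole numbers of reads per operational taxonomic unit (OTU) and sample, not normalized by the authors. The table holds 1630 OTUs, of which 1468 had a read in the 60 samples. The clustering tool, its identity threshold and any filter before deposit are not given in the sources used here. The submitters' processing notes name the mouse build mm10 without a role. The table pairs OTU identifiers with no taxon name or sequence, so identifiers are printed as they stand in the table. Another 79 columns of the table did not match a sample of these 6 groups and were not used in any step.

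Changes in single OTUs were tested with edgeR (version 4.0.16, in R 4.3.3). OTUs with at least 5 reads in at least 5 samples were kept, which left 783. Total reads served as library size with trimmed mean of M values (TMM) factors. The quasi-likelihood test was fitted over all 6 groups, which share an estimate of the spread, without a block. All adjusted p-values for single OTUs come from this edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, at a threshold of 0.05. The interaction is the AOS10 effect in HFD-STZ animals minus the AOS10 effect in untreated animals. Whole communities were compared by permutational analysis of variance of Bray-Curtis dissimilarity of read shares, with the spread around the group centre tested beside it (vegan 2.7.1, 9999 permutations). Shannon index and observed OTUs were taken from counts drawn without replacement to 32134 reads per sample, the total of the shallowest sample. Distance to control is a sample's mean Bray-Curtis dissimilarity to the control samples, leaving out the sample itself. These values were compared by two-sided permutation tests of the difference in means with 100000 resamples, adjusted by Benjamini-Hochberg over the comparisons of each measure.

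The planned genus, phylum and taxon-list tests need taxon names and were not run, so the planned OTU tests carry the report. By the rule set for that case before the data were examined, each comparison names at most 2 OTUs that rose and 2 that fell. They have the largest fold changes among OTUs past the threshold with a mean share of at least 0.1% in 1 of the groups and a difference of means or medians in the same direction. The OTU with the highest mean share in each group is described as well, a choice outside that rule and made after the values were seen. Any other OTU is said to have been chosen after its values were seen. Where a group had no read of an OTU, the fold is a lower bound against 3 counts over the pooled reads of that group. With a few reads, the ratio of pooled shares is given with its exact 95% interval. Such bounds and intervals cover counting error only.

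Depth ran from 32134 to 56112 reads per sample. The limit of 3 counts over the pooled reads of a group corresponded to a share of 5.95e-04% in HFD-STZ+control-FMT, the most deeply sequenced group, and 6.96e-04% in AOS10, the least. No pair of samples within a group agreed within sampling noise. The lowest chi-square per degree of freedom between a pair was 62.9, and all samples were kept as separate replicates. The labels do not say that samples came from separate animals or cages, so p-values measure only the spread between these samples. No cage, litter or sequencing batch is given in the labels, and none was modelled.

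The edgeR step was tested on simulated counts with the means and totals of HFD-STZ and control samples, 783 OTUs and 200 of them changed. It recovered 11% of the 4-fold and 51% of the 16-fold changes, with 8 false calls among 70. The permutation test of means gave a p under 0.05 in 4% of 200 draws without a difference. Alternatives covered the scaling (TMM with singleton pairing, total counts alone), DESeq2 (version 1.42.0, poscounts size factors), limma (version 3.58.1) on centred log-ratios with a pseudocount of 0.5, and rank-sum tests on shares. They also covered the filter on low counts, the samples in the fit, a robust prior, the number in the sample title as a block, equal depth, and other diversity indices and distances. The rank-sum test was run with 100000 permutations in place of the planned normal approximation because of tied values.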

Results

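The bacteria associated with the mouse colon were profiled by 16S rDNA sequencing in 60 samples, 10 in each of 6 groups. The series was designed to examine how faecal microbiota transplantation (FMT) acts on a colon damaged by a high-fat diet and streptozotocin (HFD-STZ). Mean depth was 46935 ± 3340 reads (SD, n = 10) in control, 43094 ± 4732 in AOS10, 47735 ± 3560 in HFD-STZ, 46982 ± 1796 in HFD-STZ+AOS10, 47534 ± 3476 in HFD-STZ+AOS10-FMT and 50444 ± 2532 in HFD-STZ+control-FMT. None of the 6 compared pairs of groups differed in total reads after adjustment (lowest adjusted p = 0.129, permutation test). AOS10 replicate 7 had 32134 reads, the fewest of all samples.

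The communities of control and AOS10 samples were dispersed and had no shared dominant OTU. The highest mean share in control was that of OTU1546 with 4.29% ± 8.49 of reads (SD, n = 10), and in AOS10 that of OTU29 with 3.20% ± 3.61. HFD-STZ was led by OTU3 with 7.59% ± 9.04, an OTU found in all 10 samples of each group. The 3 remaining groups were all led by OTU1553, with 21.4% ± 9.99 in HFD-STZ+AOS10, 17.1% ± 16.9 in HFD-STZ+AOS10-FMT and 29.6% ± 13.9 in HFD-STZ+control-FMT. Second in all 3 was OTU2, an OTU chosen after its values were seen, with 6.54% ± 4.88, 13.9% ± 5.45 and 7.93% ± 5.96. In control, AOS10 and HFD-STZ, OTU2 stood at 0.205% ± 0.383, 0.192% ± 0.25 and 0.261% ± 0.518. The mean dissimilarity between samples of a group was 0.771 in control, 0.695 in AOS10 and 0.769 in HFD-STZ, against 0.514, 0.518 and 0.513 in the 3 groups given AOS or a transplant on top of HFD-STZ.

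**Figure D1:**
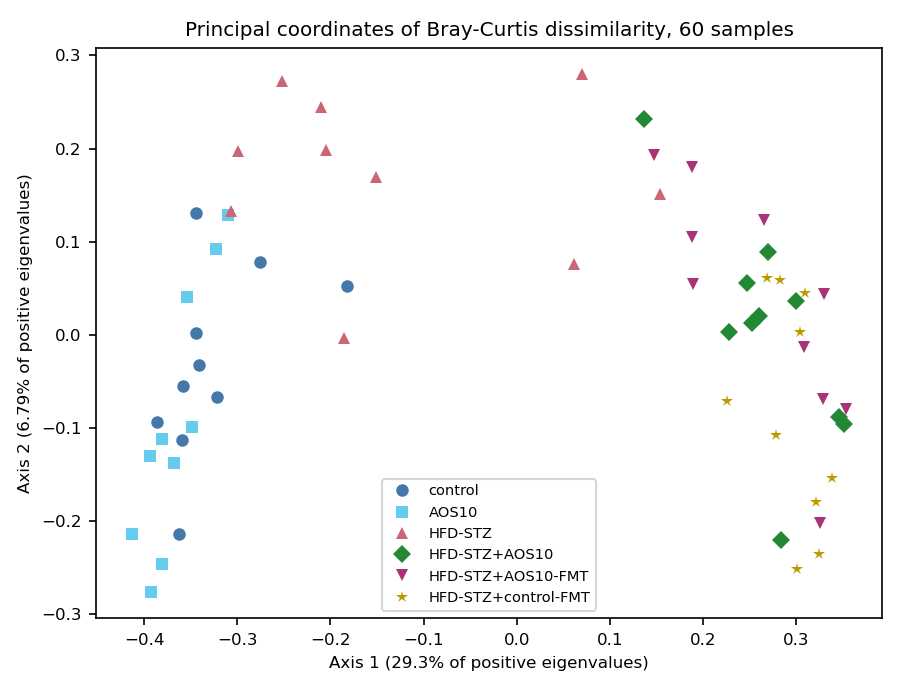
Principal coordinates of the Bray-Curtis dissimilarity of the 60 samples, each point a sample, with the group given by colour and marker and both axes unitless. On axis 1, control and AOS10 samples lie at -0.182 or below, HFD-STZ samples range from -0.307 to 0.154, and the samples of the 3 groups given AOS or a transplant on top of HFD-STZ lie at 0.137 or above.

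The effect of the high-fat diet with streptozotocin was read from HFD-STZ against control. HFD-STZ samples held fewer OTUs and much smaller shares of many OTUs of the control community. Observed OTUs fell from 517 ± 97.8 (SD, n = 10) to 397 ± 53.5, a difference of -119.1 (adjusted p = 0.0236, permutation test). With the Chao1 estimate in their place the adjusted p was 0.0563, and without HFD-STZ replicate 14 it was 0.0529. A set of 227 OTUs that made up 44.0% ± 15.8 of control reads was lower in HFD-STZ, where it made up 1.57% ± 0.762, and 87 of these OTUs had no read in any HFD-STZ sample. Another 125 OTUs rose from 1.22% ± 0.724 of reads to 26.4% ± 12.02, and 58 of them had no read in control. These shares describe OTUs selected for the difference between the same samples.

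OTU123 was found in all 10 control samples at 0.737% ± 1.03 and had no read in HFD-STZ, which makes it at least 1171-fold lower (log2 fold change -12.21, SE 1.70, adjusted p = 1.27e-05). It also had no read in any of the 3 other HFD-STZ groups and was present in all 10 AOS10 samples. OTU1546, the leading OTU of control, was carried by control replicates 10, 11 and 12 (3.05%, 16.1% and 23.8%), with 0.0202% or less in the other 7, and left 2 reads in all of HFD-STZ, a ratio of pooled shares of 10701 (95% interval 2962 to 88369; adjusted p = 1.27e-05). OTU1553 rose from 0.00115% ± 0.00228 to 2.56% ± 4.52, with a log2 fold change of 10.19 (SE 1.66, adjusted p = 1.27e-05). It was found in 9 of 10 HFD-STZ samples and in 3 of 10 control samples. OTU1627 had no read in control and was found in 6 HFD-STZ samples at a mean of 0.459% ± 0.770, at least 714-fold higher (adjusted p = 6.04e-04). These folds lean on single samples: they were 736 for OTU123 without control replicate 4, 5031 for OTU1546 without control replicate 12 (19143 and 19263 without HFD-STZ replicates 7 and 15) and 464 for OTU1627 without HFD-STZ replicate 9. The log2 fold change of OTU1553 was 9.55 without HFD-STZ replicate 2 and 11.15 without control replicate 10, and all 4 calls held.

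In all, 352 of 783 OTUs changed between HFD-STZ and control in the edgeR quasi-likelihood test, 125 up and 227 down. The excess of lower OTUs depended on the method: total counts alone kept it (137 up, 208 down), TMM with singleton pairing gave 215 up and 167 down, and DESeq2 gave 131 up and 116 down. With only OTUs that had at least 10 reads in at least 10 samples, 94 were up and 66 down, and a permutation rank-sum test on shares called 93, 18 up and 75 down. Group membership accounted for 12.3% of the squared Bray-Curtis dissimilarity (R2 = 0.123, p = 1e-04, the smallest the permutations can give, adjusted p = 1.5e-04). The spread around the group centre was 0.517 in HFD-STZ and 0.518 in control (adjusted p = 0.972). The Shannon index was 3.81 ± 0.492 in HFD-STZ and 4.11 ± 0.455 in control, a difference that did not exceed the spread (adjusted p = 0.218, permutation test).

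**Figure D2:**
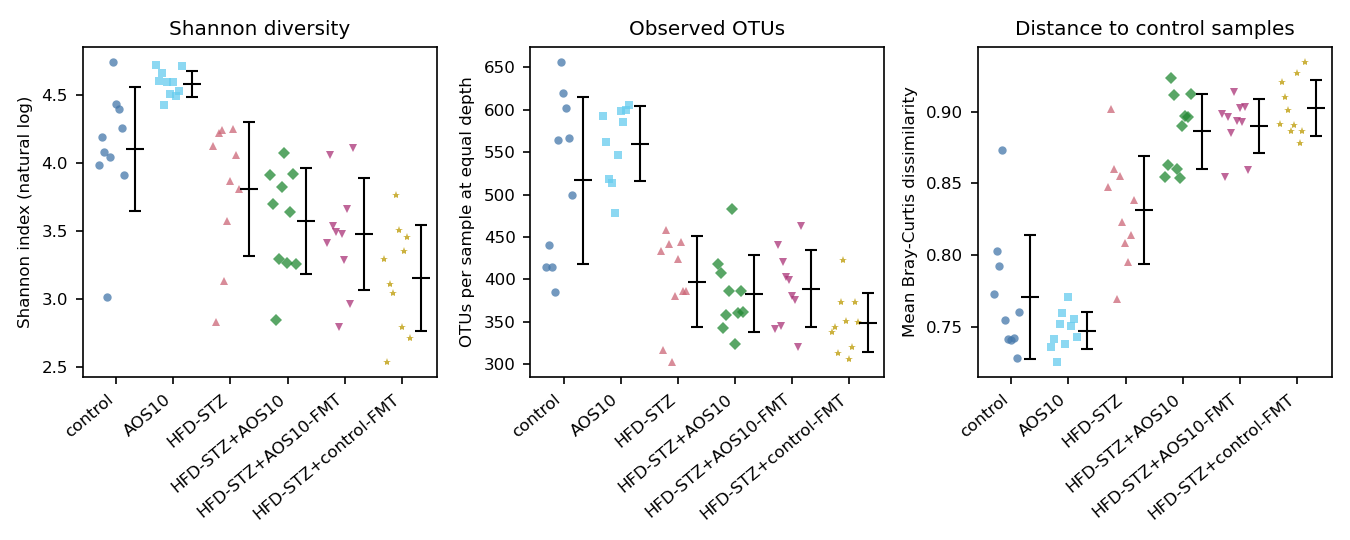
Shannon index (natural log), observed OTUs at equal depth and mean Bray-Curtis dissimilarity to the control samples, for each of the 60 samples by group; black bars give the mean and SD of 10 samples, and no vertical axis starts at 0. Mean Shannon index was highest in AOS10 (4.58) and lowest in HFD-STZ+control-FMT (3.16), and mean distance to control rose from 0.831 in HFD-STZ to between 0.886 and 0.903 in the 3 groups on the right.

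The effect of AOS alone was read from AOS10 against control. AOS10 samples were more even, while few single OTUs differed. The SD of their Shannon index was smaller than in control, a difference that was not tested. The Shannon index rose from 4.11 ± 0.455 (SD, n = 10) to 4.58 ± 0.0958 (adjusted p = 0.00564, permutation test). The share of the most abundant OTU of each sample fell from 16.7% ± 6.95 to 8.07% ± 1.91, a difference of -8.67 percentage points (adjusted p = 0.00216, permutation test). Observed OTUs were 560 ± 44.1 and 517 ± 97.8, which did not differ beyond the spread (adjusted p = 0.323, permutation test). The 227 OTUs that were lower in HFD-STZ than in control made up 40.8% ± 12.9 of reads in AOS10, close to their 44.0% in control.

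The edgeR test called 19 OTUs, 8 up and 11 down. The 8 made up 1.49% ± 1.73 of AOS10 reads and the 11 made up 0.96% ± 1.41 of control reads. OTU55 was found in 6 AOS10 samples at a mean of 0.228% ± 0.297 and left 1 read in control, a ratio of pooled shares of 1067 (95% interval 191 to 42200; adjusted p = 0.0037), or at least 319-fold without control replicate 4, which had that read. OTU1627 was at least 978-fold higher (adjusted p = 0.0132), but rested on 2 AOS10 samples, of which replicate 4 held 5.43%. Without that sample the bound was 1.23-fold and the adjusted p 0.591. OTU96 stood at 0.323% ± 0.990 in control and 0.00187% ± 0.00326 in AOS10 (log2 fold change -7.61, SE 1.93, adjusted p = 0.0167), and a single control sample, replicate 10, held 3.14%. Without it the log2 fold change was -2.61 (adjusted p = 0.430), and without AOS10 replicate 6 it was -8.26. OTU31 stood at 0.140% ± 0.401 in control and 0.0044% ± 0.00713 in AOS10 (log2 fold change -6.35, SE 1.56, adjusted p = 0.0151). In control replicate 4 it held 1.28% of reads. Without that sample the log2 fold change was -2.04 (adjusted p = 0.475), while without AOS10 replicate 4 it was -6.94. OTU31, OTU96 and OTU1627 were also not called on centred log-ratios or with the compared groups alone, nor OTU31 with total counts alone or in DESeq2. With the 2 compared groups fitted alone, 1 OTU was called, and a permutation rank-sum test called 0 (50 at an unadjusted p under 0.05, against 109 in edgeR). The whole communities did not differ beyond the spread (R2 = 0.0678, adjusted p = 0.115), and total counts alone gave 6 OTUs up and 4 down, centred log-ratios 16 up and 11 down.

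The effect of AOS given on top of HFD-STZ was read from HFD-STZ+AOS10 against HFD-STZ. The community shifted to OTU1553 and OTU2, and became more alike between samples. OTU1553 rose from 2.56% ± 4.52 of reads (SD, n = 10) to 21.4% ± 9.99 (log2 fold change 3.66, SE 1.23, adjusted p = 0.0155) and was found in all 10 samples. It is described here as the leading OTU of HFD-STZ+AOS10, a choice made after the values were seen. OTU2, chosen after its values were seen, rose from 0.261% ± 0.518 to 6.54% ± 4.88 (log2 fold change 4.45, SE 1.18, adjusted p = 0.00243). OTU10 and OTU173 had no read in HFD-STZ and were found in 4 and 7 HFD-STZ+AOS10 samples. OTU10 reached 0.804% ± 1.86, at least 1271-fold higher (adjusted p = 5.83e-04), and OTU173 reached 0.368% ± 0.512, at least 576-fold higher (adjusted p = 6.32e-04). Without replicate 9, which held 5.63%, OTU10 was at least 408-fold higher and still called, but on centred log-ratios it was not called, nor was OTU173 in DESeq2.

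OTU28 and OTU68 went the other way, from 2.32% ± 4.03 and 1.17% ± 2.33 in HFD-STZ to no read in HFD-STZ+AOS10. They were at least 3594-fold and 1847-fold lower (adjusted p = 2.09e-04 and 8.84e-05), or 1926-fold without HFD-STZ replicate 17 and 755-fold without HFD-STZ replicate 15, and both stayed called. OTU68 was present in all 10 control and all 10 AOS10 samples and in 7 HFD-STZ samples. In total 271 OTUs changed, 74 up and 197 down. The OTUs that fell made up 38.1% ± 26.4 of HFD-STZ reads and 0.998% ± 0.298 of HFD-STZ+AOS10 reads, and 87 of them had no read in HFD-STZ+AOS10. On centred log-ratios the calls were evenly split, 89 up and 89 down, and a permutation rank-sum test called 67, 38 up and 29 down.

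The distance to control grew. Mean dissimilarity to control was 0.831 ± 0.0374 in HFD-STZ and 0.886 ± 0.0262 in HFD-STZ+AOS10 (adjusted p = 0.00172, permutation test). The 227 OTUs lower in HFD-STZ than in control made up 1.88% ± 1.35 of reads, against 1.57% ± 0.762 in HFD-STZ and 44.0% in control. The 1.57% is biased low, because the OTUs were selected in these HFD-STZ samples. On OTUs called lower without the judged sample, single HFD-STZ samples held 1.06% to 23.1%. Of the OTUs changed by HFD-STZ, 20 changed in the opposite direction with AOS10 and 54 in the same direction. Independent lists of these sizes would share 52.9 and 68.9. The 68.9 counts 87 OTUs lower in HFD-STZ without a read there. These cannot be called lower again, so a shortfall cannot be read from it. These counts moved with the method: TMM with singleton pairing gave 41 and 40 (67.8 and 61.9 for independent lists), no filter 48 and 45 (58.0 and 86.0) and a permutation rank-sum test 2 and 5 (4.31 and 3.65). On centred log-ratios (14 and 33, against 25.5 and 25.5) and with the stricter filter (17 and 33, against 31.8 and 27.2) more OTUs went in the same direction than independent lists would share, unlike in the edgeR test above. Both comparisons contain the same HFD-STZ samples, and unchanged groups simulated against them shared 0. Drawn around the fitted HFD-STZ means, these groups had no difference from HFD-STZ to call and lack the error that both comparisons share. The 0 is therefore not a chance level for the real counts. With the HFD-STZ samples split between the comparisons, the medians were 8 opposite and 36 in the same direction, against 27.0 and 38.5 for independent lists of those sizes. Group membership gave R2 = 0.221 (p = 1e-04, the smallest the permutations can give, adjusted p = 1.5e-04). The spread around the group centre also differed (0.344 against 0.517, adjusted p = 3e-04), so that this test mixes position and spread. Shannon index (3.57 ± 0.389 against 3.81 ± 0.492, adjusted p = 0.245) and observed OTUs (383 ± 45.3 against 397 ± 53.5, adjusted p = 0.622) did not differ beyond the spread in permutation tests.

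**Figure D3:**
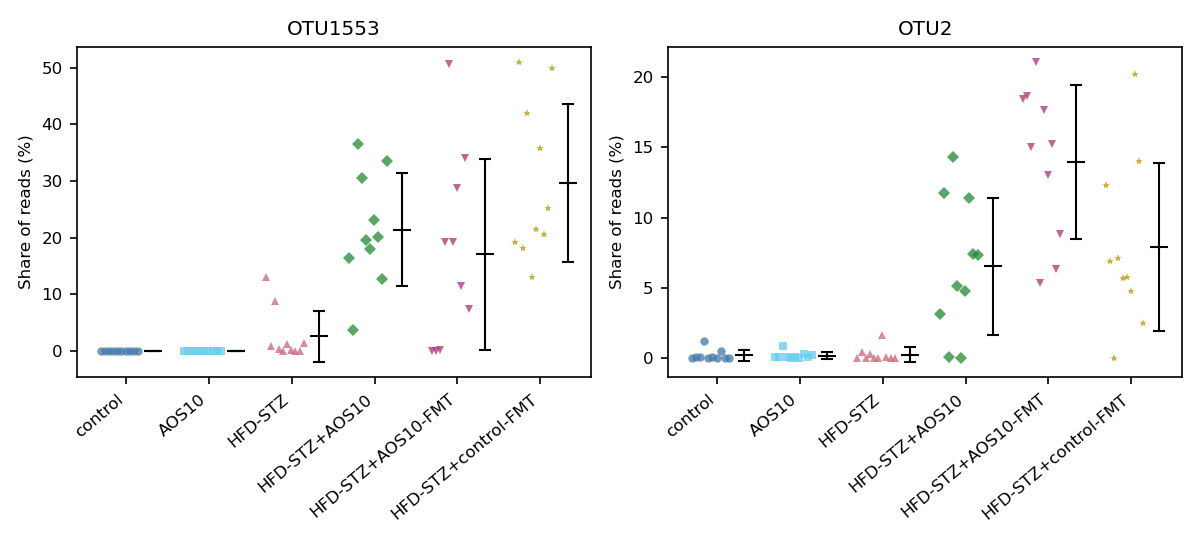
Share of reads (percent, linear axis) of OTU1553 and OTU2 in each of the 60 samples by group, with the mean and SD of 10 samples as black bars. OTU1553 averaged 2.56% in HFD-STZ and 21.4%, 17.1% and 29.6% in the 3 groups on the right, and 3 HFD-STZ+AOS10-FMT samples held 0.11% or less.

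Transplants from AOS10 donors were examined in HFD-STZ+AOS10-FMT against HFD-STZ. The same 2 OTUs rose. OTU1553 reached 17.1% ± 16.9 of reads (SD, n = 10; log2 fold change 3.45, SE 1.22, adjusted p = 0.0207), with no read in replicates 1 and 3, 0.11% in replicate 4 and 7.32% to 50.7% in the other samples. OTU2 reached 13.9% ± 5.45 (log2 fold change 5.71, SE 1.26, adjusted p = 4.78e-04) and was at 5.32% or more in all 10 samples. OTU10 was found in 7 samples at 0.766% ± 1.05, at least 1164-fold higher than in HFD-STZ (adjusted p = 5.82e-04). OTU69 was found in 4 samples at 0.169% ± 0.441 and left 1 read in HFD-STZ, a ratio of pooled shares of 891 (95% interval 159 to 35222; adjusted p = 3.97e-04). Without replicate 18, which held 1.40%, this ratio was 155, without HFD-STZ replicate 17 it was at least 268, and OTU69 stayed called both times, but on centred log-ratios it was not called.

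OTU52 and OTU1367 had no read in HFD-STZ+AOS10-FMT. They stood at 2.87% ± 4.83 and 1.70% ± 2.23 in HFD-STZ, at least 4685-fold and 2691-fold higher (adjusted p = 3.44e-04 and 2.11e-05), with OTU52 at 2780-fold without HFD-STZ replicate 16. OTU1367 was present in all 10 control and all 10 AOS10 samples, and OTU52 in 2 and 1. In total 307 OTUs changed, 99 up and 208 down, and the 208 went from 46.5% ± 27.5 of reads to 1.67% ± 1.27. Centred log-ratios gave 111 up and 105 down, and a permutation rank-sum test 46 up and 40 down. Mean dissimilarity to control was 0.890 ± 0.0189, above the 0.831 of HFD-STZ (adjusted p = 8.85e-04, permutation test). The 227 OTUs lower in HFD-STZ than in control made up 2.28% ± 1.39 of reads. Of the OTUs changed by HFD-STZ, 30 changed in the opposite direction and 57 in the same, against 61.9 and 76.1 for independent lists, 0 in simulated unchanged groups and medians of 12 and 39.5 with split HFD-STZ samples (31.0 and 40.6 for independent lists of those sizes). TMM with singleton pairing gave 50 and 47 (74.8 and 69.6 for independent lists), no filter 68 and 47 (67.3 and 91.8) and a permutation rank-sum test 3 and 1 (5.33 and 4.89). Centred log-ratios gave 23 and 32 (31.0 and 30.8) and the stricter filter 28 and 41 (40.4 and 35.3). Here too, the 76.1 counts OTUs without a read in HFD-STZ, which cannot be called lower again, and the simulated 0 is not a chance level. Group membership gave R2 = 0.243 (adjusted p = 1.5e-04), with a spread of 0.347 against 0.517 (adjusted p = 4e-04). Shannon index (3.48 ± 0.413, adjusted p = 0.181) and observed OTUs (389 ± 45.5, adjusted p = 0.711) did not differ from HFD-STZ beyond the spread in permutation tests.

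Transplants from control donors were examined in HFD-STZ+control-FMT against HFD-STZ. OTU1553 and OTU2 rose here as well, and diversity fell. OTU1553 reached 29.6% ± 13.9 of reads (SD, n = 10; log2 fold change 4.65, SE 1.29, adjusted p = 0.00362), with at least 13.1% in all 10 samples, and OTU2 reached 7.93% ± 5.96 (log2 fold change 5.33, SE 1.23, adjusted p = 7.01e-04). OTU10 was found in 9 of 10 samples at 4.82% ± 6.18, at least 7836-fold higher than in HFD-STZ (adjusted p = 1.12e-04). OTU109 was found in 4 samples at 0.325% ± 0.720, at least 517-fold higher (adjusted p = 3.83e-04). OTU28 and OTU68 had no read, as in HFD-STZ+AOS10, and were at least 3859-fold and 1983-fold lower (adjusted p = 1.75e-04 and 6.3e-05). Leaving out single samples lowered these bounds without ending a call: to 5053-fold for OTU10 (replicate 11), 179-fold for OTU109 (replicate 1), 2068-fold for OTU28 (HFD-STZ replicate 17) and 810-fold for OTU68 (HFD-STZ replicate 15). The Shannon index fell from 3.81 ± 0.492 to 3.16 ± 0.389, a difference of -0.653 (adjusted p = 0.0166, permutation test). With the Simpson index in its place the adjusted p was 0.0641.

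In total 304 OTUs changed, 100 up and 204 down, and the 204 went from 45.8% ± 28.1 of reads to 1.03% ± 0.504. Centred log-ratios gave 99 up and 98 down, and a permutation rank-sum test 46 up and 64 down. Mean dissimilarity to control was 0.903 ± 0.0195 (adjusted p = 3.6e-04 against HFD-STZ, permutation test). The 227 OTUs lower in HFD-STZ than in control made up 2.79% ± 3.18 of reads. Of the OTUs changed by HFD-STZ, 31 changed in the opposite direction and 56 in the same, against 61.6 and 75.1 for independent lists, 0 in simulated unchanged groups and medians of 11 and 38.5 with split HFD-STZ samples (32.0 and 40.6 for independent lists of those sizes). TMM with singleton pairing gave 52 and 47 (73.0 and 67.0 for independent lists), no filter 64 and 54 (66.7 and 92.8) and a permutation rank-sum test 1 and 4 (5.88 and 7.19). Centred log-ratios gave 21 and 27 (28.2 and 28.2) and the stricter filter 26 and 43 (40.7 and 36.2). Again, the 75.1 counts OTUs without a read in HFD-STZ, which cannot be called lower again, and the simulated 0 is not a chance level. Group membership gave R2 = 0.266 (adjusted p = 1.5e-04), with a spread of 0.345 against 0.517 (adjusted p = 3e-04). Observed OTUs were 349 ± 34.7 against 397 ± 53.5 (adjusted p = 0.0861, permutation test).

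**Figure D4:**
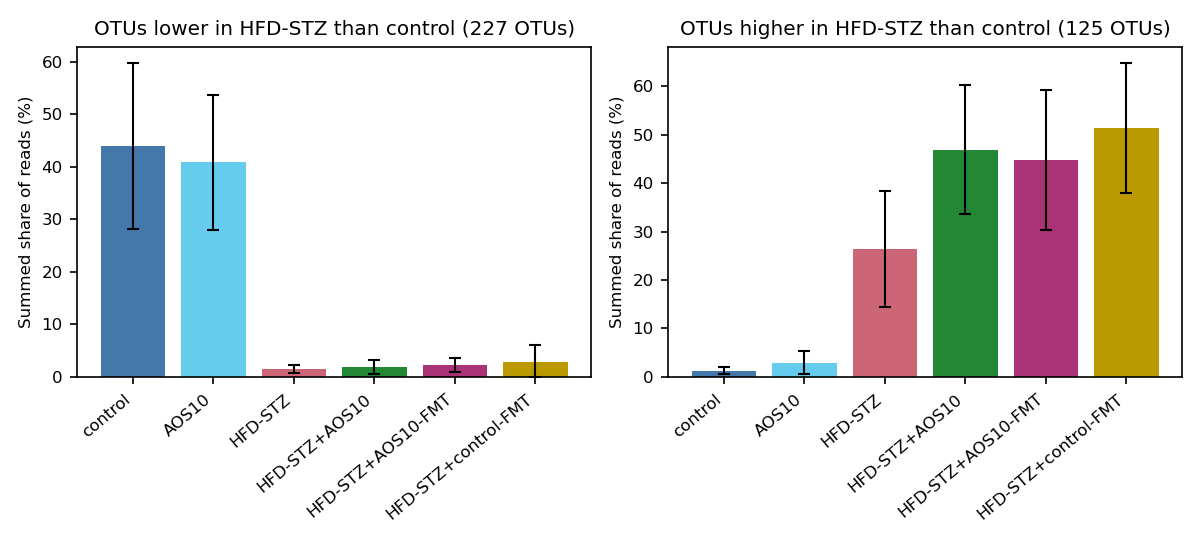
Summed share of reads (percent) of the 227 OTUs lower and the 125 OTUs higher in HFD-STZ than in control, as the mean of 10 samples per group with SD; lower error bars stop at 0. The first set stands at 44.0% in control and 40.8% in AOS10 and between 1.57% and 2.79% in all 4 HFD-STZ groups, and the second at 26.4% in HFD-STZ and 44.7% to 51.4% in the 3 groups on the right. The second set includes OTU1553, whose own mean was 2.56% in HFD-STZ and 21.4%, 17.1% and 29.6% in those 3 groups. That OTU accounts for most or all of the further rise of the set. Both sets were selected in these HFD-STZ and control samples, so the values of those groups are biased towards the difference. On OTUs called lower without the judged sample, single HFD-STZ samples held 1.06% to 23.1%. The first set therefore does not show that HFD-STZ stood level with the 3 groups on the right. Membership of the sets depends on the scaling in the edgeR test, as TMM with singleton pairing called 167 lower and 215 higher, with 292 OTUs called in the same direction under both.

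The 3 groups given AOS or a transplant on top of HFD-STZ changed many of the same OTUs against HFD-STZ. HFD-STZ+AOS10 and HFD-STZ+AOS10-FMT shared 225 calls in the same direction, HFD-STZ+AOS10 and HFD-STZ+control-FMT shared 217, and both transplant groups shared 244. Calls in opposite directions numbered 0 for each pair. Independent lists would share 61.7, 60.8 and 66.8 in the same direction, and unchanged groups simulated against the same HFD-STZ samples shared 0. With the HFD-STZ samples split between the comparisons, the median numbers were 108, 105 and 113, against 32.4, 31.6 and 34.2 for independent lists of those sizes. Across OTUs, which are not independent replicates, the fold changes correlated at r = 0.871, 0.858 and 0.881. With HFD-STZ samples split the median r was 0.626, 0.620 and 0.644, and in simulated unchanged groups r was 0.181, 0.168 and 0.164. Their covariance exceeded the simulated covariance by 9.80, 10.1 and 10.7. The simulated groups were drawn around the fitted means of these HFD-STZ samples. The simulated values, the shared count of 0 included, therefore leave out the error that the HFD-STZ samples bring to both comparisons. With no difference from HFD-STZ to call, the 0 is not a chance level for the shared calls. The mean dissimilarity between samples of different groups of these 3 was 0.527 to 0.546, near the 0.513 to 0.518 within them, while to HFD-STZ samples it was 0.777, 0.800 and 0.817. The labels do not give cages or batches, so the treatments cannot be separated from anything else these 3 groups shared.

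The donor's treatment was examined in HFD-STZ+AOS10-FMT against HFD-STZ+control-FMT. Both groups were close, with 14 OTUs called, 7 up and 7 down. OTU104 was found in 7 samples of the AOS10-FMT group at 0.422% ± 0.897 (SD, n = 10) and had no read in the control-FMT group, at least 711-fold higher (adjusted p = 0.00257; 270-fold without replicate 6). It was also found in 6 HFD-STZ+AOS10 samples, at 0.0258% ± 0.0338, and in none of the control and AOS10 samples. OTU13 stood at 3.15% ± 6.59 against 0.00898% ± 0.0202 (log2 fold change 8.44, SE 2.08, adjusted p = 0.0181), with a median of 0.00822% and a highest share of 16.4% in the AOS10-FMT group. Without that sample, replicate 4, the log2 fold change was 7.49 (adjusted p = 0.0384), without AOS10-FMT replicate 1 it was 7.70 and without control-FMT replicate 1 it was 10.10. OTU190 had no read in the AOS10-FMT group and stood at 0.367% ± 0.990 in the control-FMT group, in 4 samples, at least 561-fold lower (adjusted p = 0.0112). Without control-FMT replicate 7, which held 3.15%, it was at least 102-fold lower (adjusted p = 0.0224). OTU13 and OTU190 were not called on centred log-ratios or with the 2 groups fitted alone. OTU99 stood at 0.00169% ± 0.00216 against 0.592% ± 0.990 (log2 fold change -8.57, SE 1.62, adjusted p = 0.00113; -7.75 without control-FMT replicate 18).

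The whole communities differed (R2 = 0.119, adjusted p = 0.0186, permutation test) with a similar spread, 0.347 and 0.345 (adjusted p = 0.972). Shannon index was 3.48 ± 0.413 against 3.16 ± 0.389 (adjusted p = 0.179) and observed OTUs 389 ± 45.5 against 349 ± 34.7 (adjusted p = 0.0861), neither past the threshold in permutation tests. OTU1553 (log2 fold change -1.21, SE 1.13, adjusted p = 0.914) and OTU2 (0.39, SE 1.03, adjusted p = 1) did not differ beyond the spread. A permutation rank-sum test called 0 OTUs (46 at an unadjusted p under 0.05, against 84 in edgeR), the 2 groups fitted alone gave 5, and without HFD-STZ+control-FMT replicate 1 there were 6. Total counts alone gave 8 up and 5 down.

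The AOS10 effect was compared between HFD-STZ and untreated animals by the interaction. The Shannon index was 0.478 higher with AOS10 in untreated animals and the corresponding difference in HFD-STZ animals was -0.236, so that the effects differed by -0.714 (adjusted p = 0.0116, permutation test). For observed OTUs the effects, 43.3 and -14.5, did not differ beyond the spread (adjusted p = 0.159, permutation test). Both permutation tests shuffled AOS10 labels within each background, which stands for no AOS10 effect in either. The interaction was past the threshold for 192 OTUs, 33 with a more positive and 159 with a more negative AOS10 effect in HFD-STZ animals. OTU2 was among the 33 (log2 difference 5.76, SE 1.56, adjusted p = 0.00495), whereas OTU1553 was not called (2.42, SE 1.90, adjusted p = 0.418). On centred log-ratios the interaction called 91 OTUs, 51 more positive and 40 more negative. HFD-STZ+control-FMT, which was given no AOS, shared 217 calls with HFD-STZ+AOS10 against HFD-STZ. The interaction therefore cannot be told apart from what these groups shared besides AOS.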

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

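Of the tests in this part, those on the shared cohort and on mislabelling by OTUs chosen without each sample, by all 3 measures together, by leaving out 1 to 4 samples or as the whole cause by 5 or more were chosen after related results were seen. Removing dominant OTUs and setting distance to control at equal depth were also chosen after seeing the data. The measure on OTUs common to the control and AOS10 samples was added after the first 2 measures of mislabelling had not excluded it, the combination after all 3 had not, and leaving out sets of samples last.

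The 3 groups given AOS or a transplant on top of HFD-STZ lay farther from control than HFD-STZ alone. A few dominant OTUs and sequencing depth are argued against: without every OTU at a mean of 5% or more in any group the smallest of the 3 differences was 0.0439, and at equal depth it was 0.0546. For control or AOS10 samples mislabelled as HFD-STZ, each of 3 measures alone left some samples in the control and AOS10 range. In the OTUs higher in the 3 groups, 6 of 10 HFD-STZ samples stood above the highest control or AOS10 sample, AOS10 replicate 4 (6.90% of reads). The lowest HFD-STZ sample held 3.50% and the highest control sample 2.42%. HFD-STZ replicate 15 held 23.1% in the OTUs called lower in HFD-STZ without it (lowest AOS10 sample 22.9%). HFD-STZ replicate 17 held 94.7% of the 94 OTUs common to all 20 control and AOS10 samples (lowest control or AOS10 sample 94%). The rule written beforehand, on every set of 1 to 5 HFD-STZ samples left out, did not exclude mislabelling. For HFD-STZ+AOS10, 242 of 252 sets of 5 stayed past the threshold. Without replicates 11, 15, 16, 17 and 18, the 5 in the control and AOS10 range on a measure, its difference was 0.0255 (p = 0.0927, permutation test). As the whole cause by 1 to 4 samples, a limit set afterwards, mislabelling is argued against: with every such set left out the smallest difference was 0.0318 (highest p = 0.0352, permutation test). Yet 5 mislabelled samples are at odds with the second measure, on which 9 of 10 lay below the lowest control or AOS10 sample (replicate 17 at 1.68%, lowest control and AOS10 samples 17.2% and 20.8%). That measure left out only the judged sample, so mislabelled samples alike among themselves could still lie low on it. Judged on all 3 measures together 0 samples lay in the range, yet single mislabelled samples that add to the difference stay open, as do a mixture of material, a shared cohort and an effect of the treatments.

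The 3 groups also resembled each other and differed from HFD-STZ, which a shared cohort or batch of the 3 groups could produce as well as the treatments. Of 312 OTUs found in at least 5 HFD-STZ samples and at least 10 control or AOS10 samples, 11 had no read in any of the 30 samples of these groups. Another 9 OTUs were found in at least 15 of the 30 samples and in no other sample. A shared cohort and the treatments cannot be told apart here, because the labels tie no sample to a cage, cohort or batch. HFD-STZ itself was uneven in this respect, with 3.50% to 48.0% of reads in the 145 OTUs higher in all 3 groups than in control, against 48.5% to 83.3% in the 3 groups.

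Samples with close title numbers may share a community. Within groups, the Bray-Curtis dissimilarity rose with the difference of the title numbers, with a mean Spearman rho of 0.138 over the 6 groups (p = 0.02, permutation of numbers within groups). No single group passed the threshold after adjustment (lowest adjusted p = 0.193), and rho ran from -0.104 in HFD-STZ+control-FMT to 0.265 in AOS10. Shared housing and the order of handling are candidate sources that the labels do not separate, and no biological explanation was tested. If neighbouring samples share a source, the p-values of the comparisons are too small.

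Other splits of the samples into groups of the same sizes were drawn, 100 per comparison with the real one included. For HFD-STZ against control, 1 split gave as many called OTUs as the real one (352, highest other 196), and likewise 1 for HFD-STZ+AOS10 (271, highest other 135), HFD-STZ+AOS10-FMT (307, highest other 146) and HFD-STZ+control-FMT (304, highest other 153) against HFD-STZ and for the interaction (192, highest other 152). A chance split can be excluded for these totals at the resolution of 100 splits, but not for each called OTU. For the interaction, AOS10 labels were shuffled within each background. Its splits stand for no AOS10 effect in either background, so they do not test whether the effects are equal. For the transplant groups 2 splits gave 14 OTUs or more, the real one included (highest other 15), which meets the limit of fewer than 5 but leaves the count weak. The splits took all samples as exchangeable, so they do not exclude a shared source of neighbouring title numbers. For AOS10 against control chance cannot be excluded, as 9 of 100 splits gave 19 OTUs or more (highest other 27). The other splits still called a median of 40 OTUs for HFD-STZ against control, 7 for AOS10 against control, 46, 30 and 33 for the 3 comparisons with HFD-STZ in the order above, 0 for the transplant groups and 25 for the interaction. Whether uneven samples or chance imbalance of groups that differ made these calls was not tested.

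The AOS10 effect on the Shannon index differed between HFD-STZ and untreated animals by -0.714, and 192 OTUs had a different AOS10 effect in these backgrounds. As said above, this cannot be told apart from what HFD-STZ+AOS10 shared with the transplant groups besides AOS. Single samples far from the rest of their group were found 9 times among the groups of values tested (36 of per-sample measures and 30 of OTU shares), where chance gives about 1 in 20, and in control the distance to control and the distance within the group are a single measure counted 2 times. AOS10 replicate 7 had 32134 reads, the next sample 40963. Control replicate 4 had a Shannon index of 3.02 (next 3.91) and a dissimilarity of 0.873 to the other control samples (next 0.803). Without it the Shannon difference between AOS10 and control was 0.357 and 10 OTUs were called in place of 19. OTU1627 held 5.43% of reads in AOS10 replicate 4 (next 0.00718%), OTU96 held 3.14% in control replicate 10 (next 0.0625%), and OTU10 had 0 reads in HFD-STZ+control-FMT replicate 13 (next 0.859%). OTU55 in control replicate 4 (0.00203%) and OTU69 in HFD-STZ replicate 17 (0.00216%) were single reads in groups otherwise at 0.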

How the results depend on the processing

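The genus, phylum and taxon-list alternatives were not run, since they need taxon names, and the alternatives planned for genera were run on OTUs. Leaving out samples, removing dominant OTUs and setting distance to control at equal depth were chosen after seeing the data. Bray-Curtis R2, which has no direction, kept its side of the threshold in all 18 alternatives. Distance to control kept its direction and side in all 12. These alternatives used Jaccard, Aitchison or equal depth among others, and both results also held without any single sample. R2 did not keep its order: HFD-STZ+AOS10 against HFD-STZ exceeded HFD-STZ against control by Bray-Curtis and fell below it by Jaccard. The Shannon index kept direction and side in 11 of 12 alternatives and observed OTUs in 16 of 18. With the Simpson index, HFD-STZ+control-FMT against HFD-STZ was -0.0731 and not past the threshold. With Chao1, HFD-STZ against control was -127.1 and not past the threshold, and HFD-STZ+AOS10-FMT against HFD-STZ, not called in either form, turned to 13.8. The cause was not tested. Single named OTUs kept direction and call in 199 alternatives and lost the call in 31. This tally leaves out the rank-sum test and settings in which the OTU was not tested. The rank-sum test called 0 OTUs for AOS10 against control and between the transplant groups, so it called none of the OTUs named there.

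Counts of changed OTUs moved most. Between HFD-STZ and control (352), 224 were called on centred log-ratios, 93 by rank sum, 160 with the stricter filter and 556 without a filter. Between AOS10 and control (19), there were 10 with total counts alone, 0 by rank sum, 2 with the stricter filter, 77 without a filter, 1 with the compared groups alone and 12 at equal depth. For HFD-STZ+AOS10 (271), HFD-STZ+AOS10-FMT (307) and HFD-STZ+control-FMT (304) against HFD-STZ, rank sum gave 67, 86 and 110 and the stricter filter 152, 195 and 198. Centred log-ratios gave 178 and 197 for HFD-STZ+AOS10 and HFD-STZ+control-FMT. Between the transplant groups (14), there were 8 on centred log-ratios, 0 by rank sum, 7 with the stricter filter, 5 with the compared groups alone and 9 at equal depth. The interaction (192) gave 91 on centred log-ratios and 126 with the stricter filter. Stricter and absent filters tested 412 and 1468 OTUs in place of 783; other causes were not tested. TMM with singleton pairing shifted the median log2 fold change of HFD-STZ against control by 1.08, and total counts alone shifted that of HFD-STZ+control-FMT against HFD-STZ by -0.42.

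With the title number as a replicate block, 66, 0, 1, 80, 48 and 1 OTUs were called in the 6 comparisons and 1 in the interaction (AOS10 against control had 60 at an unadjusted p under 0.05). The numbers do not pair the samples: deviations of same-numbered samples correlated at -0.0045 on average, and 2 of 56 samples matched their own number best.

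Without single samples, AOS10 against control gave 10 to 20 OTUs, with 10 without control replicate 4, 11 without control replicate 10 and 12 without control replicate 7 or AOS10 replicate 6. The transplant groups gave 6 to 15, with 6 without HFD-STZ+control-FMT replicate 1 and 9 without HFD-STZ+AOS10-FMT replicate 6. Observed OTUs differed by -133.7 to -103.6 between HFD-STZ and control, and the call ended without HFD-STZ replicate 14 (-108.6). For HFD-STZ+control-FMT against HFD-STZ the range was -58.6 to -41.4, past the threshold without HFD-STZ replicate 7 or 14 or HFD-STZ+control-FMT replicate 7. Between the transplant groups it was 31.5 to 47.9, past the threshold without HFD-STZ+AOS10-FMT replicate 18 or HFD-STZ+control-FMT replicate 7. In simulated counts 11% of 4-fold changes were recovered, so OTUs not called may still differ. Of the 70 calls there 8 were false, so some called OTUs may not differ.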

Other observations

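The test on transplanted OTUs in this part was chosen after the shares of the OTUs lower in HFD-STZ had been seen.

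OTUs typical of the donors' groups were next looked for in the recipients. A set of 31 OTUs was found in at least 8 of 10 control samples and in at most 1 of 10 HFD-STZ samples. At equal depth, control samples held 25.9 ± 3.21 of these 31 OTUs (SD, n = 10), HFD-STZ+control-FMT samples 0.7 ± 0.823 and HFD-STZ+AOS10 samples, which had no transplant, 0.9 ± 0.994. The difference of -0.2 did not exceed the spread (adjusted p = 1, permutation test). For AOS10 donors, 45 OTUs met the same rule. AOS10 samples held 37.2 ± 5.18 of them, HFD-STZ+AOS10-FMT samples 1.7 ± 0.949 and HFD-STZ+AOS10 samples 1.6 ± 1.58, a difference of 0.1 (adjusted p = 1, permutation test). The 31 OTUs made up 5.87% of control reads and 0.078% of HFD-STZ+control-FMT reads, and 0 of them reached 5 of 10 recipients. The 45 OTUs made up 9.10% of AOS10 reads and 0.0224% of HFD-STZ+AOS10-FMT reads, and 1 of them reached 5 recipients, against 0 in HFD-STZ+AOS10. The hypothesis that donor OTUs missing from HFD-STZ were taken up in number by the recipients is thus not borne out in colon tissue at this depth. The donors themselves were not analysed here, and the control and AOS10 samples stand in for them.

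OTU10 and OTU1553, which rose in both transplant groups, were rare or absent in control and AOS10. OTU10 had no read in control, AOS10 or HFD-STZ, and OTU1553 stood at 0.00115% ± 0.00228 of control and 0.00351% ± 0.00882 of AOS10 reads (SD, n = 10), in 3 samples of each. Both were also found in HFD-STZ+AOS10, OTU10 in 4 and OTU1553 in all 10 samples.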
